A study of Saccharomyces cerevisiae Vin13 with 18 samples.

How the data were processed

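Total RNA (100 ng per sample) from 3 biological replicates of each scale and day was amplified, and 7.5 µg of the biotin-labelled product was hybridised to an array for S. cerevisiae and S. pombe, giving 18 arrays. Per the labels the authors used the Affymetrix Expression Console with RMA, whose versions are not given in the sources used here. The deposited values are probe set summaries in units of intensity on a linear scale, between 4.79 and 39396. The plan, written before the data were examined, took them to be log2 values, as RMA gives. Log2 was therefore taken here, and every difference below is on that scale.

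The table held 10928 probe sets. Left out of the gene tests were 166 controls, 1 probe set listed with several genes and 1746 listed with a gene outside the S. cerevisiae reference named below. On that ground the 1746 were taken to be S. pombe probe sets and are called so here. Also left out were 3517 probe sets without a listed gene, which cannot be assigned to either species. The remaining 5498 probe sets stood for 5449 S. cerevisiae genes. For the 47 genes with more than 1 probe set, the one with the highest mean over all arrays was kept. Over those 47 genes the probe sets differed in sign for 6, 4 and 8 genes in the scale comparisons of days 2, 5 and 10, and were apart by over 1 log2 unit for 0, 3 and 3. Gene names, coding lengths and neighbours came from an S. cerevisiae reference of 6477 genes.

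Depth was read as signal over background: a gene counted as above background where its log2 value exceeded 4.40, the 95th percentile of the S. pombe probe sets. By that measure 5401 genes lay above background in at least 1 group mean and 38 on no array. Where a gene lay at or below background on every array of a group, its fold was given as a bound against that level.

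Differences were tested with limma 3.58.1 in R 4.3.3 (with data.table version 1.17.8), with 6 group means fitted to all 18 arrays, 12 residual degrees of freedom and the default empirical Bayes prior. There were 9 comparisons: large against small scale on each day, day 5 against day 2 and day 10 against day 5 at each scale, and the difference between the scales in each of these changes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The p-values measure the spread between the biological replicates that the labels name, pooled over the 6 groups. That spread was unequal: the median SD per gene ran from 0.083 in small-scale day 2 to 0.178 in large-scale day 10. Gene lists, 45 in number and fixed before the data were examined, were tested with limma's camera against all other genes at a preset correlation of 0.01, with adjustment over the lists. Of 1482 entries written 1422 matched a measured gene, and lists needed at least 5. Members of a list were also counted with p adjusted over the list alone. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.

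Genes were named by a rule fixed beforehand: the 8 largest rises and 8 largest falls of a scale comparison, or 5 of each for day comparisons and interactions, among called genes with a standard symbol, above background and, outside the interactions, with no overlap between the groups. Up to 3 called members per direction were taken from a list. The ranking over all 3 days was chosen after the values were seen.

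The alternatives tried were a repeated quantile normalization over S. cerevisiae probe sets, centring each array on its median, leaving out dim genes, the most variable probe set per gene, all 5498 listed probe sets, a trended and robust prior, array weights, only the groups compared in the fit, a 2-fold change required as well, an estimated correlation within lists, the replicate number as a fixed block, the replicate number within a scale as a random block, and leaving out each array in turn. Removal of a smooth trend on coding length (lowess span 0.3) was added after seeing the data. The method was tested on simulated data, with 50 genes changed per size among 5449: changes of 0.5, 1, 2 and 4 log2 units were called in 54%, 92%, 100% and 100% of cases, with 13 false calls. The 36 proteasome genes were also shifted, by 0.5. Noise was drawn independently for each gene, and far fewer genes changed than were called between the scales on day 2. The shares and false calls therefore need not carry over to the data, and correlation between genes was not simulated.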

Results

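VIN13, a commercial wine strain of Saccharomyces cerevisiae, was fermented in Chardonnay must at 20 °C in microaerobic vials of 80 ml (small scale) and in commercial tanks of 300 L (large scale). Both were inoculated to an OD600 of 0.1. Cells were sampled on day 2 in exponential growth, on day 5 in early stationary phase and on day 10 in late stationary phase. The labels give 3 biological replicates per scale and day, so the data are 6 groups of 3 arrays, 18 in all. RNA was measured on an Affymetrix array that carries probe sets for S. cerevisiae and for the fission yeast Schizosaccharomyces pombe. The comparisons ask how gene expression differed between the scales on each day, how it changed with time at each scale, and whether that change differed between the scales.

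The deposited intensities ran from 4.79 to 39396 over the 18 arrays. Signal over background was judged from the 1746 probe sets taken to be of S. pombe, whose 95th percentile was an intensity of 21.1 (log2 4.40). Between 5357 and 5387 of the 5449 S. cerevisiae genes lay above that level on each array. The lowest correlation across genes between arrays of a group was 0.974 for large-scale day 10 and lay between 0.990 and 0.995 for the other 5 groups. The number of arrays per group limits the precision of every value. Genes given below as largest, most or next in order are so among called genes with a standard symbol, and some genes without one changed more.

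The arrays grouped by scale and day, apart from large-scale day 10 replicate 2. The first principal component carried 49.9% of the variance and the second 31.8%. Large-scale day 2 lay at one end of the first component (mean score -63.8 ± 2.69, SD, n = 3) and small-scale day 10 at the other (40.3 ± 2.31). Large-scale day 10 replicate 2 stood apart from its group, with a first score of 2.01 against 22.9 and 18.5. On the first 2 components it lay nearer to the large-scale day 5 arrays than to the rest of its group. The control probe sets that compare the 3′ with the 5′ part of a transcript, a sign of RNA or cDNA length, differed with day and scale on average. Their mean log2 difference was 1.13 ± 0.01, 1.52 ± 0.06 and 1.82 ± 0.07 (SD, n = 3) at small scale on days 2, 5 and 10, and 0.99 ± 0.06, 1.28 ± 0.08 and 1.45 ± 0.08 at large scale. The control genes did not move alike. At small scale ACT1 had group means of 0.72, 0.61 and 0.64 on days 2, 5 and 10. From day 2 to day 10 at small scale, WBP1 rose from 1.28 to 1.53 up to 3.16 to 3.73 over the arrays. SPT15 fell from 1.77 to 1.94 down to 1.30 to 1.37. The mean log2 signal of the S. pombe probe sets was 3.40 ± 0.002 at small scale on day 2 and between 3.46 and 3.53 in the other 5 groups.

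**Figure D1:**
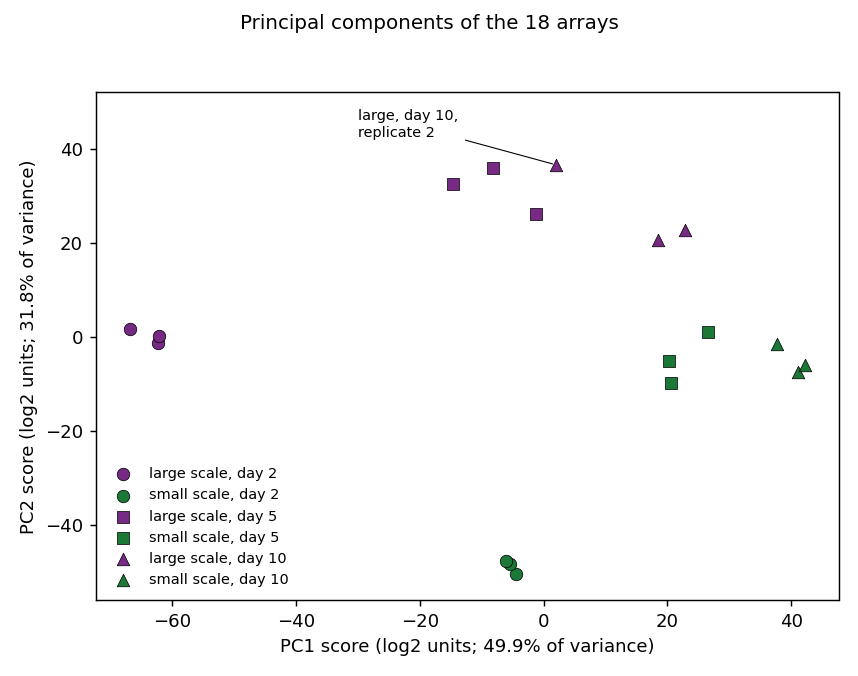
Scores of the 18 arrays on the first 2 principal components (log2 units), with colour for the scale and marker shape for the day. Large-scale day 10 replicate 2 has scores of 2.01 and 36.6, against 22.9 and 22.8, and 18.5 and 20.5, for the rest of its group. It lies nearer to large-scale day 5 replicate 2, at -8.25 and 35.9. Apart from this array the groups lie apart.

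On day 2, 4211 of the 5449 genes differed between the scales, 2081 higher and 2130 lower in the tanks. The largest difference was in ROX1 (YPR065W), a heme-dependent repressor of hypoxic genes, whose log2 signal was 13.17 ± 0.09 (SD, n = 3) in vials and 6.03 ± 0.75 in tanks. Its log2 difference was -7.14 (SE 0.34, adjusted p = 5.47e-11). The largest rise was in AGP1 (YCL025C), a broad-range amino acid permease, with 10.50 ± 0.17 in vials and 14.24 ± 0.15 in tanks (log2 difference 3.74, SE 0.13, adjusted p = 1.93e-12). Genes of ribosome assembly, respiration and sterol synthesis were mostly lower in tanks, and genes of sugar use and the cell wall mostly higher, as counted next.

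Of 103 measured ribosome biogenesis genes, 86 were lower in tanks, 5 higher and 12 not called, with a median log2 difference of -1.22 (adjusted p = 3.01e-10, and adjusted p = 0.555 with an estimated correlation). Among them NOP16 was lower at -4.45, EBP2 at -4.02 and FCF2 at -3.98, while TIF6 was higher at 0.82. Outside the list, CGR1 and RRP36 also act in ribosome assembly. RRP36 differed by -5.20 (SE 0.48). CGR1 was at background on every day 2 tank array and was at least 22.7-fold lower in tanks, a bound taken against the background level (adjusted p = 1.61e-08). Of 127 cytosolic ribosomal protein genes, 98 were lower, 5 higher and 24 not called (median -0.97, adjusted p = 0.585 with an estimated correlation), with RPL39 at -2.62 and RPS10A at -2.58. Mitochondrial ribosome genes were lower in 38 and higher in 13 of 66 cases (median -0.61, adjusted p = 0.655 with an estimated correlation), led by RSM18 at -3.25. Ribosomal genes are short, and short genes outside the ribosome lists were also lower in tanks: the median log2 difference was -0.32 for 834 genes with under 600 nt of coding sequence and 0.11 for 3553 genes with 900 nt or more.

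CYC1, which encodes the main cytochrome c, differed by -5.75 (SE 0.28), CYB2, a mitochondrial lactate dehydrogenase, by -5.98 (SE 0.31) and SUE1, which acts in the turnover of cytochrome c, by -5.96 (SE 0.22). Of 39 genes of the respiratory chain and ATP synthase, 26 were lower, 6 higher and 7 not called (median -0.75, adjusted p = 0.555 with an estimated correlation). QCR6 was at -3.57 and COX7 at -3.47, against 1.23 for NDE2, an external NADH dehydrogenase. TCA cycle genes went the other way, with 13 of 17 higher and 2 lower (median 0.62, adjusted p = 0.555 with an estimated correlation). In ergosterol biosynthesis 20 of 27 genes were lower and 4 higher (median -0.70, adjusted p = 0.555 with an estimated correlation). HMG1, a rate-setting reductase of the pathway, was lower at -3.96 and IDI1 at -3.13, whereas the hypoxic isozyme HMG2 was higher at 1.23 and the acyltransferase ARE1 at 1.88. The anaerobic and hypoxic list was split, with 18 of 26 genes higher, among them AAC3 at 1.74 and the sterol importer AUS1 at 1.64, and 5 lower, among them ROX1 and the repressor MOT3 at -3.46. Its median was 0.70 and its mean 0.19 (adjusted p = 0.555 with an estimated correlation).

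Among the rises, all 10 measured maltose and sucrose genes were higher in tanks (median 1.56, adjusted p = 0.555 with an estimated correlation), with the invertase gene SUC2 at 2.48 and the maltose activator MAL33 at 2.44. Cell wall and mannoprotein genes were higher in 36 and lower in 3 of 49 cases (median 0.61, adjusted p = 0.555 with an estimated correlation), led by DSE2 at 2.60 and DSE4 at 2.50, glucanases of daughter cell separation. Trehalose and glycogen genes were higher in 17 of 20 cases and lower in 1, with the glycogen synthase GSY1 at 2.25 (adjusted p = 0.555 with an estimated correlation). Of 24 vitamin genes 19 were higher and 2 lower (adjusted p = 0.555 with an estimated correlation), with BIO5 at 2.30 and BIO3 at 2.12, and BPL1, the biotin protein ligase, differed by 2.63. Thiamine and pyridoxine genes were higher in 14 and lower in 3 of 20 cases (adjusted p = 0.555 with an estimated correlation), with SNO1 at 2.67. All 13 measured seripauperin genes were higher (median 0.71, adjusted p = 0.555 with an estimated correlation), PAU3 at 2.84, but these near-identical copies share sequence and single members are uncertain. The zinc transporter ZRT2, the vacuolar sorting gene VPS73, the glycosylation enzyme ALG7 and the ammonium permease MEP3 were also among the largest rises, at 2.83, 2.63, 2.62 and 2.62. Nitrogen catabolite repressed genes were not called as a list, with 6 higher and 21 lower of 39 (adjusted p = 0.0567). Its members ranged from AGP1 and MEP3 among the largest rises to PUT1, the proline oxidase, at -5.66 (SE 0.29) and the proline permease PUT4 at -4.97. ECM13, of unknown function, differed by -5.37 (SE 0.32).

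These calls come from limma at a Benjamini-Hochberg adjusted p, and 1742 of the 4211 genes also changed by 2-fold or more, 686 higher and 1056 lower. For 82.2% of all genes the 3 tank values and the 3 vial values did not overlap, against 10% by chance, and every gene named here as a largest rise or fall is among them. Adjusted over the list alone, the counts above were the same except for thiamine and pyridoxine genes (15 higher and 3 lower). In all, 18 of 45 lists were called with a preset correlation of 0.01 and 0 with an estimated one. Of the 10 divisions of the 6 arrays into groups of 3, the real one included, 4 gave at least 18. That share does not test chance, since the other divisions mix tank and vial arrays. Repeating the quantile normalization over S. cerevisiae probe sets moved the median of all genes from -0.01 to 0.11, so the list medians are to be read against that shift.

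On day 5, 3374 genes differed between the scales, 1805 higher and 1569 lower in tanks. Heat shock and ribosomal protein genes were lower in tanks and seripauperin genes higher, as counted next. The largest fall was in DIP5 (YPL265W), a permease of dicarboxylic amino acids, with a log2 signal of 12.61 ± 0.28 (SD, n = 3) in vials and 8.20 ± 0.22 in tanks (log2 difference -4.41, SE 0.42, adjusted p = 2.61e-07). SOV1 (YMR066W), a mitochondrial protein, rose most, from 7.13 ± 0.17 in vials to 10.09 ± 0.24 in tanks (log2 difference 2.95, SE 0.18, adjusted p = 2.03e-09).

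Of 32 heat shock and chaperone genes 25 were lower in tanks, 2 higher and 5 not called (median -1.01, adjusted p = 0.069 with an estimated correlation). BTN2, which sorts misfolded proteins, differed by -4.07 (SE 0.19), the inducible chaperone SSA4 by -2.75 and HSP82 by -2.66, while the heat shock factor HSF1 was higher at 0.40. The HSF1 call was lost without large-scale day 5 replicate 2 (HSF1 adjusted p = 0.0956) and without some other single arrays. Of 127 ribosomal protein genes 111 were lower and 0 higher, or 112 lower adjusted over the list alone (median -0.77, adjusted p = 0.622 with an estimated correlation), with RPL39 at -3.31. Ribosome biogenesis genes were lower in 59 and higher in 12 of 103 cases, or 62 and 12 adjusted over the list alone (median -0.47, adjusted p = 0.727 with an estimated correlation), with UTP30 at -2.37 and MRT4, a ribosome assembly factor outside the list, at -3.74 (SE 0.15). Short genes outside the ribosome lists had a median of -0.27 and long ones 0.13.

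Of 13 seripauperin genes 12 were higher and 0 lower (median 1.57, adjusted p = 0.34 with an estimated correlation), PAU24 at 2.37, with single members uncertain as before. In the anaerobic and hypoxic list 16 of 26 genes were higher and 6 lower (median 0.83, adjusted p = 0.614 with an estimated correlation), ROX1 again lowest at -2.73. TCA cycle genes were higher in 15 of 17 cases, peroxisomal fatty acid oxidation genes in 14 of 21, thiamine and pyridoxine genes in 15 of 20 and vitamin genes in 16 of 24. Lower members numbered 1, 1, 2 and 1, and adjusted p = 0.622 with an estimated correlation for each of these lists. CIT3 at 1.15, SPS19 at 2.12, SNZ1 at 1.73 and BNA2 at 1.32 led them. Oxidative stress genes were higher in 20 and lower in 4 of 37 cases (adjusted p = 0.622 with an estimated correlation), led by OYE3, an NADPH oxidoreductase, at 2.31. Cell wall genes were higher in 25 and lower in 6 of 49 cases (adjusted p = 0.727 with an estimated correlation), the flocculin FLO11 being lowest at -2.04. Aroma genes were higher in 14 and lower in 4 of 26 cases (adjusted p = 0.727 with an estimated correlation), among them ARO10, a decarboxylase of the fusel alcohol pathway, at 2.04 and AAD4 at 2.32, or 3.04 for AAD4 with its most variable probe set.

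The other largest rises were NBL1 at 2.79, the sporulation kinase SMK1 at 2.72, the sphingolipid phosphatase YSR3 at 2.60, PRM2 at 2.52, the amino acid permease BAP3 at 2.38 and DDI3 at 2.32, whose probe set is shared with a near-identical copy and is uncertain. The other largest falls were PUT1 at -4.07, the histone chaperone CHZ1 at -3.84, OPI10 at -3.43, CYC1 at -3.39 and the prefoldin subunit YKE2 at -3.33. Of the 3374 genes 755 changed by 2-fold or more, 275 higher and 480 lower, which turns the balance of directions. The groups did not overlap for 66.2% of genes, and list counts adjusted over the list alone were the same where none are given. Of 45 lists 12 were called with the preset correlation and 0 with an estimated one.

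On day 10, 3196 genes differed between the scales, 1759 higher and 1437 lower in tanks. Heat shock genes had the lowest adjusted p of the 45 lists, as given next, and BTN2 (YGR142W) the largest fall, from 14.17 ± 0.09 (SD, n = 3) in vials to 9.59 ± 0.51 in tanks (log2 difference -4.58, SE 0.19, adjusted p = 1.25e-11). SOV1 again rose most, from 6.96 ± 0.20 in vials to 10.61 ± 0.47 in tanks (log2 difference 3.64, SE 0.18, adjusted p = 1.46e-10).

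Of 32 heat shock and chaperone genes 27 were lower in tanks, 2 higher and 3 not called (median -1.03, adjusted p = 1.05e-13). This list held its call with the correlation estimated (adjusted p = 0.0324 with an estimated correlation), which no other list in any comparison did. SSA4 differed by -3.97 (SE 0.11) and the cyclophilin CPR6 by -2.87, with HSF1 higher at 0.35. The HSF1 call was lost without large-scale day 10 replicate 1 (HSF1 at 0.18, adjusted p = 0.255). It was also lost with the replicate block (HSF1 adjusted p = 0.061) and without several other single arrays. All 13 seripauperin genes were higher (median 1.23, adjusted p = 0.37 with an estimated correlation), PAU24 at 2.05. Oxidative stress genes were higher in 24 and lower in 3 of 37 cases (median 0.42, adjusted p = 0.515 with an estimated correlation), with the sulfiredoxin SRX1 at 2.19 and OYE3 at 2.14. Cell wall genes were higher in 29 and lower in 4 of 49 cases (adjusted p = 0.679 with an estimated correlation), with GAS2 at 2.09 and the flocculins FLO11 and FLO9 lower at -1.93 and -1.67.

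Ribosome biogenesis genes were lower in 50 and higher in 10 of 103 cases (median -0.37, adjusted p = 0.75 with an estimated correlation), with UTP30 at -2.03. Ribosomal protein genes were lower in 35 and higher in 1 of 127 cases, or 24 and 0 adjusted over the list alone (median -0.16, adjusted p = 0.849 with an estimated correlation). Short genes outside the ribosome lists had a median of -0.24 and long ones 0.11. TCA cycle genes were higher in 14 of 17 cases (15 adjusted over the list alone), vitamin genes in 16 of 24 (17 alone), peroxisomal genes in 13 of 21, thiamine and pyridoxine genes in 13 of 20 (14 alone) and aroma genes in 15 of 26. Lower members numbered 0, 0, 0, 1 and 4, with adjusted p = 0.679 with an estimated correlation for each of these lists. SNO1 at 2.05, ARO10 at 2.15 and RIB7, an enzyme of riboflavin synthesis, at 1.40 stood out. Purine and pyrimidine genes were higher in 17 and lower in 2 of 33 cases (adjusted p = 0.75 with an estimated correlation), and the anaerobic and hypoxic list in 15 and 5 of 26 (adjusted p = 0.515 with an estimated correlation).

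The other largest rises were NBL1 at 3.53, BSC1 at 3.46, RRT5 at 3.33, MBR1 at 3.17, the RNA-binding protein PHO92 at 3.14, RTT10 at 2.71 and DDI3 at 2.64. The other largest falls were OPI10 at -4.26 (SE 0.09), YAR1, a chaperone of a ribosomal protein, at -3.83, MRT4 at -3.80, the splicing factor PRP46 at -3.72, DIP5 at -3.35 and CHZ1 at -3.20. The value of CHZ1 was -2.33 with array weights and -2.23 without large-scale day 10 replicate 2. Of the 3196 genes 663 changed by 2-fold or more, 292 higher and 371 lower, which turns the balance of directions, and the groups did not overlap for 61.6% of genes. List counts adjusted over the list alone were the same where none are given, except that the anaerobic list then had 16 higher members, and 13 of 45 lists were called.

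**Figure D2:**
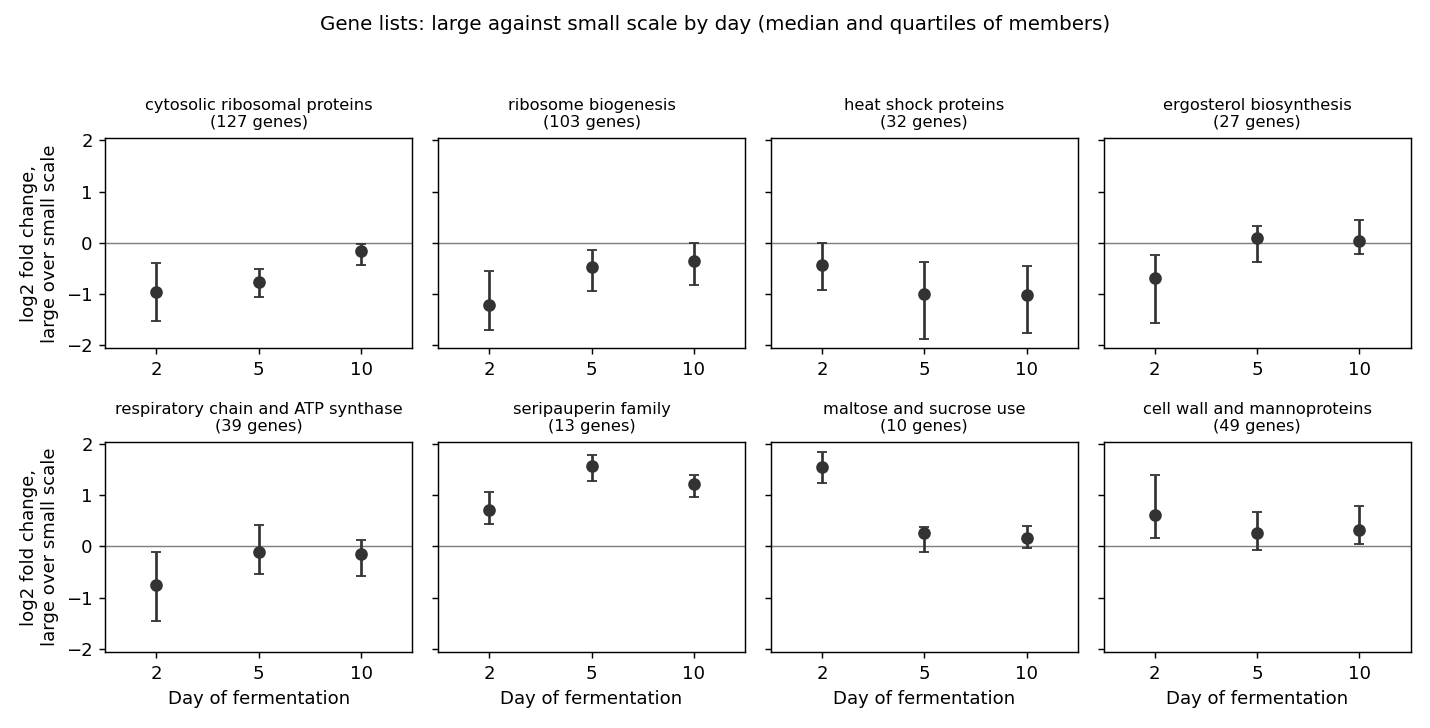
Median (point) and quartiles (bars) of the log2 difference, large over small scale, of the measured members of 8 gene lists on days 2, 5 and 10. The heat shock medians were -0.43, -1.01 and -1.03 and the maltose and sucrose medians 1.56, 0.26 and 0.17, while the ergosterol medians on days 5 and 10 and the respiratory median on day 5 changed sign between scalings.

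The difference between the scales was related across the days. The log2 differences of day 5 and day 10 correlated at r = 0.876 (Spearman 0.868) across the 5449 genes, those of day 2 and day 5 at 0.628 (0.584) and those of day 2 and day 10 at 0.534 (0.532), though genes are not independent replicates. No array entered more than one of these differences. On all 3 days 938 genes were higher in tanks and 838 lower, against 223 and 162 if the calls of the days were independent, and 323 were called on every day in mixed directions. Ranked by the smallest of the 3 differences, a ranking chosen after the values were seen, DDI3 came first among the rises, with 2.55, 2.32 and 2.64 on days 2, 5 and 10. MUP3, a methionine permease, followed with 2.46, 1.88 and 1.86, and ARO9, an aromatic aminotransferase, had 1.68, 1.83 and 1.83. CHZ1 came first among the falls with -4.69, -3.84 and -3.20, narrowly ahead of PUT1. Its place is uncertain, since its day 10 value was -2.33 with array weights and -2.23 without large-scale day 10 replicate 2. PUT1 had -5.66, -4.07 and -3.20, and DAL80, a repressor of nitrogen genes, was lower at -4.24, -3.17 and -2.99.

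**Figure D3:**
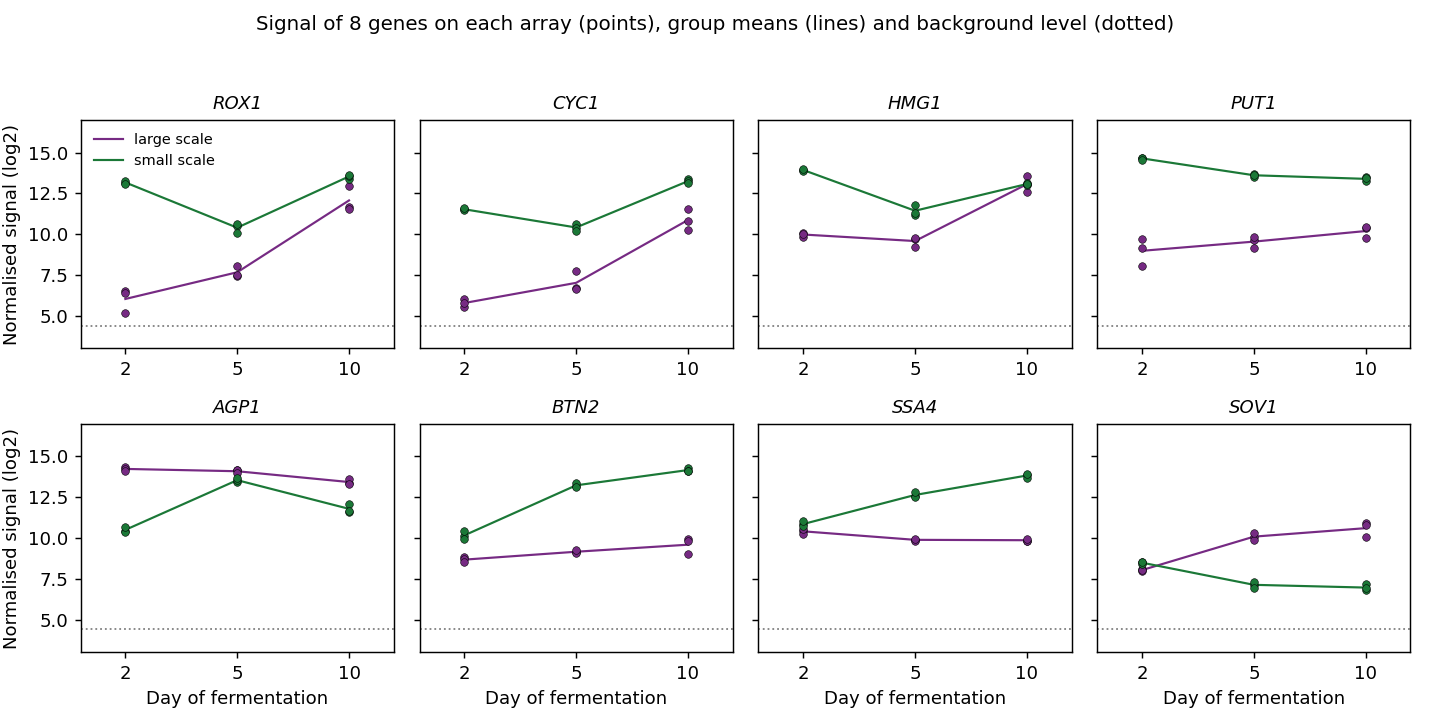
Normalised log2 signal of 8 genes on each array (points) with group means (lines) by day, purple for large and green for small scale, and the background level of 4.40 dotted. ROX1 and CYC1 rose from day 5 to day 10 at both scales, while BTN2 and SSA4 rose with time at small scale and were lower at large scale on days 5 and 10.

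In the vials, 3684 genes changed from day 2 to day 5, 1442 rising and 2242 falling. Chaperone genes rose and sterol genes fell, as counted next. URN1 (YPR152C), a splicing factor, rose most, from 8.05 ± 0.09 (SD, n = 3) to 12.55 ± 0.26 (log2 change 4.51, SE 0.13, adjusted p = 1.06e-13), and CYB5 (YNL111C), cytochrome b5, fell most, from 14.48 ± 0.07 to 11.21 ± 0.28 (log2 change -3.27, SE 0.19, adjusted p = 3.76e-10). Of 32 heat shock genes 27 rose, 1 fell and 4 were not called (median 1.08, adjusted p = 0.0558 with an estimated correlation), led by APJ1 at 3.94 and SIS1 at 3.15, while HSP12 fell at -0.46, a call lost without small-scale day 5 replicate 1 (HSP12 adjusted p = 0.0789). Of 27 ergosterol genes 26 fell and 0 rose (median -1.56, adjusted p = 0.794 with an estimated correlation), with ERG8 at -2.60 and HMG1 at -2.50. Mitochondrial ribosome genes fell in 48 and rose in 5 of 66 cases (adjusted p = 0.794 with an estimated correlation), and respiratory genes fell in 23 and rose in 3 of 39 (adjusted p = 0.865 with an estimated correlation). Ribosome biogenesis genes fell in 68 and rose in 4 of 103 cases (adjusted p = 0.865 with an estimated correlation), led by BFR2 at -1.77. Of 18 gluconeogenesis genes 10 rose and 4 fell (adjusted p = 0.794 with an estimated correlation), led by the activators ADR1 at 3.35 and CAT8 at 2.20.

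The other largest rises in vials were GIT1, a transporter of glycerophosphoinositol, at 4.28, GAC1, a phosphatase subunit that promotes glycogen storage, at 3.38 and ISF1 at 3.37. The other largest falls were TPA1 at -3.21, MSC7 at -3.03, the copper transporter CTR3 at -2.82 and ROX1 at -2.77. List counts adjusted over the list alone were the same for the lists given. Of the 3684 genes 1135 changed by 2-fold or more, 470 up and 665 down, and 13 of 45 lists were called with the preset correlation and 0 with an estimated one. Repeating the quantile normalization moved the median of all genes from -0.16 to -0.04.

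From day 5 to day 10 in the vials 1674 genes changed, 614 rising and 1060 falling. Among genes with a standard symbol ROX1 rose most, from 10.40 ± 0.27 (SD, n = 3) to 13.54 ± 0.15 (log2 change 3.14, SE 0.34, adjusted p = 7.13e-06), followed by CYC1 at 2.84, the mitochondrial J-protein JID1 at 2.70, FAT3, which acts in fatty acid uptake, at 2.65, and CYB5 at 2.17. AGP1 fell most, at -1.76 (SE 0.13), followed by YPS5 at -1.52, GIT1 at -1.39, COS7 at -1.31 and RIM9 at -1.27. Of 27 ergosterol genes 16 rose and 1 fell, or 18 and 3 adjusted over the list alone (adjusted p = 0.603 with an estimated correlation), with ARE2 at 1.83. Heat shock genes rose in 19 and fell in 2 of 32 cases, or 21 and 2 adjusted over the list alone (adjusted p = 0.113 with an estimated correlation), with SSA4 at 1.19. Ribosomal protein genes fell in 54 and rose in 0 of 127 cases, or 75 and 0 adjusted over the list alone (median -0.39, adjusted p = 0.845 with an estimated correlation). In the meiosis and sporulation list 13 of 44 genes rose and 1 fell, or 14 and 1 adjusted over the list alone (adjusted p = 0.0862 with an estimated correlation), with SPO20 at 1.96 and RIM4 at 1.75. Amino acid permease genes fell in 11 of 27 cases and rose in 0, with the same counts adjusted over the list alone (adjusted p = 0.845 with an estimated correlation). Respiratory genes rose in 17 and fell in 6 of 39 cases, or 20 and 13 adjusted over the list alone (adjusted p = 0.603 with an estimated correlation).

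The share of rising genes among those called in vials from day 5 to day 10 was 36.7%, but 50.4% once a trend on coding length was removed, an alternative chosen after seeing the data, and 129 of the 144 genes that changed by 2-fold or more rose. Array weights raised the count to 3019, and the number of lists called was 11, or 19 without small-scale day 10 replicate 3.

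In the tanks, 3996 genes changed from day 2 to day 5, 1864 rising and 2132 falling. ARO10 (YDR380W) rose most, from 7.83 ± 0.11 (SD, n = 3) to 12.78 ± 0.02 (log2 change 4.95, SE 0.10, adjusted p = 1.03e-15). BIO5 (YNR056C), a transporter of a biotin precursor, fell most, from 12.78 ± 0.09 to 9.46 ± 0.20 (log2 change -3.32, SE 0.16, adjusted p = 7.31e-11). Of 24 vitamin genes 18 fell and 1 rose (median -0.69, adjusted p = 0.972 with an estimated correlation), among them the biotin transporter VHT1 at -3.08, with RIB1 rising at 1.78. Of 27 ergosterol genes 22 fell and 1 rose (median -0.74, adjusted p = 0.972 with an estimated correlation), led by ERG24 at -2.27. Heat shock genes rose in 21 and fell in 7 of 32 cases, or 21 and 8 adjusted over the list alone (median 0.49, adjusted p = 0.972 with an estimated correlation), with APJ1 at 2.88 and HSP82 falling at -1.07. The other largest rises were the replication factor SLD2 at 4.22, RGS2, a regulator of G-protein signalling, at 3.87, PHO92 at 3.81 and the cell wall integrity regulator RLM1 at 3.34. The other largest falls were DSE2 at -3.04, VBA4 at -2.94 and VPS73 at -2.75. Of the 3996 genes 1531 changed by 2-fold or more, 752 up and 779 down. Only 3 of 45 lists were called, 5 without large-scale day 2 replicate 3 and 0 with an estimated correlation.

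From day 5 to day 10 in the tanks 2123 genes changed, 836 rising and 1287 falling. Among genes with a standard symbol ROX1 rose most, from 7.67 ± 0.33 (SD, n = 3) to 12.07 ± 0.79 (log2 change 4.40, SE 0.34, adjusted p = 1.87e-07), followed by JID1 at 3.98, CYC1 at 3.85, CYB2 at 3.55 and HMG1 at 3.49. With array weights CYC1 was at 3.15 and CYB2 at 2.82. GAL7, an enzyme of galactose use, fell most, at -1.60 (SE 0.17), followed by ATP10 at -1.47, BAP2 at -1.34, BAP3 at -1.31 and RRT6 at -1.31. Ergosterol genes rose in 15 and fell in 2 of 27 cases, or 16 and 2 adjusted over the list alone (median 0.52, adjusted p = 0.919 with an estimated correlation). Ribosomal protein genes rose in 24 of 127 cases and fell in 0, or 7 and 0 adjusted over the list alone (median 0.18, adjusted p = 0.919 with an estimated correlation), with RPL39 at 1.72. Outside the ribosome lists, short genes also had a positive median, 0.14, against -0.10 for long ones. Respiratory genes rose in 20 and fell in 8 of 39 cases, with the same counts adjusted over the list alone (adjusted p = 0.919 with an estimated correlation), COX7 at 1.53 and QCR6 at 1.49 among them. As in vials, heat shock genes rose, in 13 and against 3 falls of 32, and meiosis genes in 13 against 7 of 44 (adjusted p = 0.919 with an estimated correlation for both). The change differed between the scales for neither the respiratory nor the heat shock list (adjusted p = 0.436 and 0.212 at the preset correlation). Amino acid permease genes fell in 16 and rose in 1 of 27 cases, or 18 and 1 adjusted over the list alone, and proteasome genes fell in 16 of 36 and rose in 0 under either adjustment (adjusted p = 0.919 with an estimated correlation for both). Changes of 2-fold or more numbered 206, of which 188 were rises. The share of rising genes was 39.4%, or 51.2% with the trend on coding length removed, and the count was 3257 with array weights and 1156 with the arrays of these 2 groups alone in the fit.

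The time courses of the scales were set against each other across genes. The log2 changes from day 2 to day 5 correlated at r = 0.543 (Spearman 0.533) between vials and tanks, and those from day 5 to day 10 at 0.681 (0.622), with no array in common. Between day 2 and day 5, 943 genes rose at both scales against 493 if the calls were independent, and 1395 fell against 877. A test of the difference itself found that 3204 genes changed differently from day 2 to day 5, 1794 more upward in tanks and 1410 more downward. The interaction was largest for ECM13, at 5.61 (SE 0.46, adjusted p = 8.23e-08), where the vials fell from 13.33 ± 0.02 to 10.74 ± 0.14 (SD, n = 3) and the tanks went from 7.96 ± 1.02 to 10.98 ± 0.10. ROX1 at 4.41, the pheromone-regulated gene PRM5 at 4.29, FMP48 at 3.66 and CTR3 at 3.50 followed. On the negative side stood OPI10 at -3.27 (SE 0.12, adjusted p = 2.80e-11), AGP1 at -3.19, YHC3 at -3.06, URN1 at -3.06 and GIT1 at -3.05.

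Among the 15 lists called for this interaction, heat shock genes were lower in 22 and higher in 2 of 32 cases, or 23 and 2 adjusted over the list alone (median -0.60, adjusted p = 0.599 with an estimated correlation), with HSP82 at -2.64. Mitochondrial ribosome genes were higher in 43 of 66 cases and lower in 1, or 44 and 1 adjusted over the list alone, and ergosterol genes in 22 and 2 of 27 under either adjustment (adjusted p = 0.762 with an estimated correlation for both), with IDI1 at 2.90. Higher and lower here mean a change more upward or more downward in tanks, not a rise or fall. Ergosterol genes fell at both scales, in 26 of 27 cases in vials and 22 in tanks. Mitochondrial ribosome genes rose in 21 and fell in 22 cases in tanks. Ribosome biogenesis genes were higher in 62 and lower in 3 of 103 cases under either adjustment (adjusted p = 0.801 with an estimated correlation). Respiratory genes were higher in 26 and lower in 2 of 39 cases, and maltose and sucrose genes lower in 9 and higher in 1 of 10, under either adjustment (adjusted p = 0.762 with an estimated correlation for both). Of the 3204 genes 1177 reached 2-fold, 702 upward and 475 downward.

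From day 5 to day 10 the change differed between the scales for 268 genes, 143 more upward in tanks and 125 more downward. MZM1 (YDR493W), a mitochondrial protein that acts in assembly of the respiratory chain, was highest at 2.87 (SE 0.22, adjusted p = 1.28e-06), rising in tanks from 9.88 ± 0.05 (SD, n = 3) to 13.05 ± 0.38, while the vial means were 10.11 ± 0.24 and 10.41 ± 0.12. RRT5 at 2.08, HMG1 at 1.85, RPL39 at 1.61 (adjusted p = 0.0499) and CYB2 at 1.58 followed, but the calls of RPL39 and CYB2 were lost with only the groups compared in the fit (RPL39 adjusted p = 0.125, CYB2 adjusted p = 0.120) and without most single arrays. With array weights the value of CYB2 was 0.78 (adjusted p = 0.116) and that of HMG1 1.21. The lowest were YLH47 at -2.64 (SE 0.18, adjusted p = 2.69e-07), PRP46 at -2.52, SPO20 at -1.91, the polyamine enzyme SPE2 at -1.74 and the mating gene PRM1 at -1.55. Ribosomal protein genes were higher in 12 and lower in 0 of 127 cases, or 76 and 0 adjusted over the list alone (median 0.58, adjusted p = 0.991 with an estimated correlation). The count of 268 genes depended on single arrays: it was 706 without large-scale day 10 replicate 2, the array that stood apart, and 176 without small-scale day 10 replicate 2. Array weights gave 1690 genes, the arrays of the 4 groups alone 146 and a 2-fold change 75.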

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

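The tests of coding length and of large-scale day 10 replicate 2, and the comparison of early with late changes, were chosen only after the result was seen, while the tests of fermentation stage and of RNA integrity were written before. The change over time differed between the scales by a test of the difference itself. From day 2 to day 5 this held for 3204 genes and 15 lists, and from day 5 to day 10 for 268 genes and 4 lists, but with an estimated correlation 0 lists were called in either interval. The genes named for the earlier interval were ECM13 (5.61), ROX1 (4.41), PRM5 (4.29), FMP48 (3.66), CTR3 (3.50), IDI1 (2.90), OPI10 (-3.27), AGP1 (-3.19), YHC3 (-3.06), URN1 (-3.06), GIT1 (-3.05) and HSP82 (-2.64), all as log2 interactions. Those of the later interval were MZM1 (2.87), RRT5 (2.08), HMG1 (1.85), RPL39 (1.61), CYB2 (1.58), YLH47 (-2.64), PRP46 (-2.52), SPO20 (-1.91), SPE2 (-1.74) and PRM1 (-1.55).

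Random splits of the 12 arrays into 4 groups do not test these counts, because they mix the differences between scales and between days into the groups, so chance is neither excluded nor shown for the interactions. Their values are given for completeness. From day 2 to day 5, 3 of 100 splits, the real one included, reached 3204 genes (highest other 3524) and 37 reached 15 lists (highest other 22). From day 5 to day 10, 11 of 100 reached 268 genes (highest other 3371, several times the real count, which points to a structure of the samples) and 96 reached 4 lists (highest other 19).

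For the other comparisons the 10 divisions of 6 arrays are too few for a share under 0.05. Every division but the real one also mixes arrays of the 2 groups. Part of the real difference then stays in the comparison and the rest enters the spread. The counts of those divisions therefore do not show what chance gives, for genes or for lists. The real gene counts and the highest others were 4211 and 0 for the scales on day 2, 3374 and 0 on day 5, 3196 and 1 on day 10, 3684 and 0 for day 5 against day 2 in vials, 1674 and 1 for day 10 against day 5 in vials, 3996 and 0 for day 5 against day 2 in tanks, and 2123 and 1173 for day 10 against day 5 in tanks. Each real gene count was reached by 1 division, the real one. The 1173 came from the division that put large-scale day 10 replicate 2 with day 5 replicates 1 and 2. For lists the real counts and highest others were 18 and 20, 12 and 16, 13 and 19, 13 and 19, 11 and 19, 3 and 10, and 9 and 16 in the same order, reached by 4, 7, 7, 8, 7, 9 and 3 of the 10 divisions.

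Signal also appeared in data outside the comparisons. Of the 3517 probe sets without a listed gene, 543 lay above the S. pombe background in at least 1 group mean, and 240, 129 and 103 of these differed between the scales on days 2, 5 and 10. By comparison, 151 of the 1746 S. pombe probe sets lay above that level in a group mean. Counted above it or not, 340, 168 and 138 of the 3517 differed on those days, and 79, 13 and 5 of the 1746. Some of the 543 would thus be expected from the choice of level alone. The species targeted by the probe sets without a listed gene is not given in the sources used here.

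A difference in fermentation stage on the same day was weighed first for the differences between the scales. The test took the correlation across genes with a change over time that shares no array with the difference. It was -0.387 (small scale) and -0.515 (large scale) on day 2 with the changes from day 5 to day 10, -0.138 and -0.180 on day 5 with those from day 2 to day 10, and -0.0427 and 0.0221 on day 10 with those from day 2 to day 5. On days 2 and 10 the interval tested is not the one an offset would follow. The early change in vials was hardly related to the late one in tanks (r = 0.0682). The other way round r was 0.328, above the bound of 0.3 given next, so early and late changes were related unevenly. The bounds set beforehand were an absolute r of 0.3 or more for a difference in stage and below 0.1 against it. Day 2 met the first bound and day 10 the second, while the day 5 values lie between them. Because of the intervals, a limit raised only after the result was seen, the outcomes of days 2 and 10 are taken to decide nothing. A difference in stage and the scale itself cannot be told apart on any of the 3 days.

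The lower ribosomal genes were weighed against the lower signal of short genes in tanks. With the trend on coding length removed, the ribosomal protein list on day 2 kept its call at adjusted p = 1.98e-07 and ribosome biogenesis at 1.22e-11, which argues against that trend as the whole cause. Over all alternatives these values ranged from 5.23e-09 to 0.585 and from 1.22e-11 to 0.555, the highest with an estimated correlation. Within groups, the signal of short relative to long genes followed the 3′ minus 5′ control difference at r = 0.557 over 18 arrays (permutation p = 0.0623, Spearman 0.459, p = 0.119, and r = 0.632 without the 2 farthest arrays). The Pearson r met the bound set beforehand for RNA integrity as the cause. On each day, the group means of the control difference and of short relative to long signal were also both lower in tanks. RNA integrity may thus contribute to the short-gene tilt. The number of arrays, and control genes that did not move alike, keep this open.

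Large-scale day 10 replicate 2 was weighed as a day 5 array with a wrong label and as a sample of poor RNA. Arrays were placed along the small-scale change from day 5 to day 10 over 1674 genes, scaled so that the mean of the large-scale day 5 arrays is 0 and the mean of the other 2 large-scale day 10 arrays is 1. Replicate 2 lay at 0.729, and the day 5 arrays between -0.09 and 0.06, which on this axis argues against a day 5 array. On the first 2 principal components, by contrast, replicate 2 lay nearer to the large-scale day 5 arrays than to the rest of its group. Its mean 3′ minus 5′ difference of 1.41 lay within the 1.19 to 1.55 of the other large-scale day 5 and day 10 arrays. This argues against RNA integrity as read from that mean. A tank that ran behind the others stays open, as untested.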

How the results depend on the processing

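Removal of the coding-length trend was chosen only after the result was seen, and the other alternatives were fixed before the data were examined. Gene counts stayed within 1.5 times the reported ones, apart from those below, with repeated quantile normalization, median centring, dim genes left out, the most variable probe set, every listed probe set, the trended and robust prior and the coding-length trend removed. No named gene changed direction under any alternative run, but the calls of HSF1 on days 5 and 10, of HSP12 in vials and of RPL39 and CYB2 in the later interaction were each lost under several, single arrays left out included. Requiring a 2-fold change gave 1742, 755 and 663 genes for the scales on days 2, 5 and 10, 1135 and 144 for the vials (day 5 against 2, then 10 against 5), 1531 and 206 for the tanks, and 1177 and 75 for the interactions, since fewer genes pass a second threshold. Among these 89.6% rose from day 5 to day 10 in vials and 91.3% in tanks. An estimated correlation within lists left 0 lists called in 8 comparisons and 1, heat shock genes, for the scales on day 10.

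Array weights gave 3019 genes for day 10 against day 5 in vials, 3257 in tanks and 1690 for the interaction from day 5 to day 10, and only the groups compared in the fit gave 1156 in tanks and 146 for that interaction. For it 7 lists were called with the quantile normalization repeated and 7 with the coding-length trend removed. The cause was not tested.

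Leaving out 1 array moved the lists called for day 10 against day 5 in vials over 8 to 19 (19 without small-scale day 10 replicate 3) and for day 5 against day 2 in tanks over 3 to 5 (5 without large-scale day 2 replicate 3). For the interaction from day 5 to day 10 the lists ranged from 1 (without large-scale day 5 replicate 3) to 10 (without small-scale day 5 replicate 3), with 8 without large-scale day 5 replicate 1 or small-scale day 10 replicate 3. Its genes ranged from 176 (without small-scale day 10 replicate 2) to 706 (without large-scale day 10 replicate 2). The cause was not tested.

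Pairing by replicate number was examined, since the labels number the replicates without saying whether a number names a vessel. The rule for pairing was a correlation above 0.1 for all arrays with the same number, and none of the 7 comparisons met it. In none did all arrays with the same number correlate above every pair with different numbers, although single pairs did. With the replicate block the counts were 4179, 3314 and 3132 for the scales on days 2, 5 and 10, 3643 and 1595 in vials, 4005 and 2086 in tanks, and 3168 and 289 for the interactions. As a random block the replicate number within a scale, treated as if it named a vessel, had a consensus correlation of -0.0189.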

Other observations

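The tests of isoform pairs and of neighbours on day 10 were chosen only after the result was seen. The test of neighbours from day 2 to day 5 in vials was written before its own result, but after YAR1 had drawn attention to the pattern. Genes of oxygen-dependent and hypoxic isoforms were compared as pairs, since cells exchange one for the other with oxygen. On day 2 the aerobic member was lower relative to the hypoxic one in 4 of 5 pairs. HMG1 and HMG2 differed most, at -3.96 and 1.23, and CYC1 and CYC7 were both lower, at -5.75 and -1.55. HYP2 was at -1.93 and ANB1 at 0.58, and PET9 at -0.46 and AAC3 at 1.74, while COX5A at -1.17 fell less than COX5B at -1.63. The same held in 4 of 5 pairs on day 5 and 5 of 5 on day 10, but several members were then not called. On day 10 HMG1 was at -0.01 and HYP2 at -0.26, neither called, and COX5A at -0.58 had turned below COX5B at -0.17. The difference within a pair was not itself tested on any day. A candidate explanation is that more oxygen reached the cells in the vials. The pairs were picked with the pattern in view, and 4 of 5 on day 2 leaves the explanation open.

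Genes that share an intergenic region with a called heat shock gene were examined in 2 comparisons only. On day 10 all 7 divergent neighbours of heat shock genes that were lower in tanks were lower as well, chosen here after their values were seen: YAR1 beside HSP82, LCB5 beside HSP60, LST8 beside SIS1, TAD2 beside KAR2, TAH11 beside SSC1, EFB1 beside SSA1 and MTQ1 beside YDJ1. Their median log2 difference was -0.87, and 0.3% of 10000 random sets of divergent genes had a median as low. Without YAR1, which drew attention to the pattern, 6 of 6 were lower (median -0.85, 0.31% of random sets). In vials from day 2 to day 5, where heat shock genes rose, 6 of 7 such neighbours rose with YAR1 left out (median 0.79, 0.63% of random sets as high), LCB5 not being called. All of them but MPS2, beside HSF1, were also in the day 10 test, so the genes were largely the same. The random sets came from 2406 divergent genes, a pool not limited to genes whose partner had changed the same way. Their shares thus cannot tell a link to heat shock from divergent pairs that change together in general. Shared regulatory sequence that links some genes of other functions to the heat shock response stays a hypothesis, found and tested largely on the same data.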
